A study of Olea europaea with 12 samples.

How the data were processed

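The series holds 12 RNA-seq libraries of olive fruit mesocarp, 3 at each of 17, 21, 26 and 30 WAF. Per the labels' protocols, total RNA was extracted with a CTAB protocol and a column kit with DNase treatment, and libraries were sequenced on the DNBseq platform. The deposited values are FPKM per gene and library as computed by the authors, rounded to 2 decimals. HISAT2 2.0.4, StringTie 1.0.4, Bowtie2 2.2.5 and RSEM are named, per the submitters' processing notes, with no role for each tool. The genome build and annotation are not given in the sources used here, so no coordinates are printed. Whether the libraries kept strand is not given either, so reads of overlapping antisense genes may not have been told apart. The labels give the samples of an age the letters A, B and C and do not say that they came from separate trees. P-values therefore measure only the spread between these samples, which may be technical in part.

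Of the 51008 genes in the table, 37991 carry a gene ID with a description, and all of them matched the reference gene table by ID with the same symbol. The other 13017 have no reference gene ID and no description, so those that passed the filter were tested but are not named. Gene names are those of the file, and most "-like" endings and words such as "putative" or "probable" were left out. A name therefore does not establish the function of a gene. The sums of FPKM per library ranged from 790578 to 845585. FPKM are scaled values and not counts, and their depth could not be recovered. In a check of 1486 genes with low values, only 11.7 to 17.0% of the ratios between libraries lay within 0.1 on the log2 scale of the most frequent one. Counts were thus not used, and no interval or detection limit for counting error is given. Genes with near-identical copies, such as those of ribosomal proteins, histones and light-harvesting proteins, are uncertain, since the estimation of values may split shared reads between copies.

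Genes with an FPKM of at least 1 in at least 3 libraries were kept, which left 26131. Each was fitted with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean for each of the 4 ages over all 12 libraries, 8 residual degrees of freedom and an empirical Bayes variance with a trend on abundance (prior degrees of freedom 4.32). The comparisons were 30 with 17, 21 with 17, 26 with 21 and 30 with 26 WAF. A moderated F test over the 4 ages gave the genes that changed at all. All p-values of genes are 2-sided limma tests with Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. Adjusted p-values of gene lists come from limma's camera, which compares the members with all other tested genes, with its preset inter-gene correlation of 0.01 and adjustment over 40 lists and 4 comparisons. The test was repeated with a correlation estimated per list. Data handling used data.table (version 1.17.8), pandas 2.3.3 and numpy 2.4.6.

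The 40 gene lists were fixed by patterns in the gene descriptions before the data were examined, as were the design, the comparisons, the alternatives and the rule for named genes. The genes named are, per comparison, the 5 with the largest rise and the 5 with the largest fall among those with an adjusted p under 0.05, a mean FPKM of at least 10 in the higher group, no overlap between the 3 libraries of each age, and a description that is not empty, uncharacterized, hypothetical or unknown. For each list described gene by gene, they are also the 3 tested members with the highest mean FPKM over the 12 libraries, whatever their test. To these come, per list and comparison, the members with the largest rise and the largest fall among those with an adjusted p under 0.05 and a mean FPKM of at least 5 in the higher group. Lists given by their counts alone have no named members. Some members match a list's pattern without the function its name states, and the test was repeated without them, an alternative chosen after the data were seen.

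Alternatives were a pseudocount of 0.1, no filter, a mean FPKM of at least 5, TPM scaling, median-of-ratios scaling, library weights, a fit of only the 2 ages compared, the replicate letter as a block, and each library left out in turn. The procedure was tested on simulated data in which 200 of the 26131 genes, all with a mean FPKM of at least 5, changed by a known size. The noise was drawn independently per gene, and no other gene changed. For 30 with 17 WAF the procedure recovered 97.0% of the genes changed by 0.5 on the log2 scale. The recovered shares at that size were 94.0% for 21 with 17 WAF, 92.5% for 26 with 21 WAF and 94.0% for 30 with 26 WAF. False calls among the unchanged genes of each run numbered 12, 6, 12 and 5. In the real data 56.1 to 73.9% of genes were called per comparison, so the simulation does not give the error rates of these calls. GO terms of the file with 10 to 500 tested genes, 569 in all, were tested with camera after the lists had been seen.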

Results

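RNA was sequenced from the mesocarp, the oil-bearing flesh of the fruit, of the olive Olea europaea. The trees were of the cultivar Koroneiki, a Greek oil cultivar, and stood in a field in Western Greece. Fruits were taken at 4 ages during maturation, given as weeks after flowering (WAF). The ages were 17, 21, 26 and 30 WAF, with 3 libraries (A, B and C) each and 12 in all. At each age the submitters picked fruits alike in colour, size and shape. The deposited table gives FPKM values (fragment numbers scaled for transcript length and library total) for 51008 genes, of which 37991 carry a gene identifier and a description. The FPKM of a library summed to between 790578 and 845585. The number of reads behind the values is unknown, so depth sets no stated limit here. After a filter on low values 26131 genes were tested with limma on log2(FPKM + 1), so a log2 change understates the change of genes with low FPKM. Values are means ± SD of 3 libraries per age (n = 3) unless stated otherwise. The median of a gene list is that of its members' log2 changes. Largest changes are those among described genes that passed the test, with a mean of at least 10 FPKM in the higher group and no overlap between the libraries of both ages. Within a list they are those among members that passed, with at least 5 FPKM.

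Libraries of the same age resembled each other more than libraries of different ages. Pearson correlations of log2(FPKM + 1) across genes, which are not independent replicates, were 0.992 to 0.996 over the 12 pairs of the same age. They were 0.888 to 0.972 over the 54 pairs of different ages, lowest between 17 and 30 WAF. The first 3 principal components held 63.1%, 21.0% and 8.56% of the variance. Library C at 30 WAF listed 36754 genes above 0, against 38351 to 39524 in the other 11 libraries. The 10 most abundant genes took 7.07 to 7.12% of the summed FPKM at 17 WAF, 13.6 to 13.9% at 21 WAF, 9.40 to 9.56% at 26 WAF and 7.80 to 7.93% at 30 WAF.

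Over the 4 ages 23483 of the 26131 tested genes (89.9%) changed at an adjusted p under 0.05 in limma's moderated F test. Of these, 8432 had their highest mean at 17 WAF, 4280 at 21 WAF, 2227 at 26 WAF and 8544 at 30 WAF. With median-of-ratios scaling 4057 genes had their highest mean at 26 WAF, and with a stricter filter 5344 had it at 17 WAF and 2831 at 21 WAF. From one age to the next, 689 genes rose in all 3 intervals and 707 fell in all 3. These counts were 791 and 544 with median-of-ratios scaling, and 580 and 782 with TPM scaling. As deposited, a further 3442 genes fell from 21 to 26 WAF and rose from 26 to 30 WAF, and 1491 did the opposite. Which of these 2 groups is larger depends on scaling, since median-of-ratios scaling gave 2015 and 2425. The median residual SD per gene was 0.080 on the log2 scale. Many changes were small, as the median absolute log2 change of all tested genes was 0.21 to 0.37 over the 4 comparisons.

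**Figure D1:**
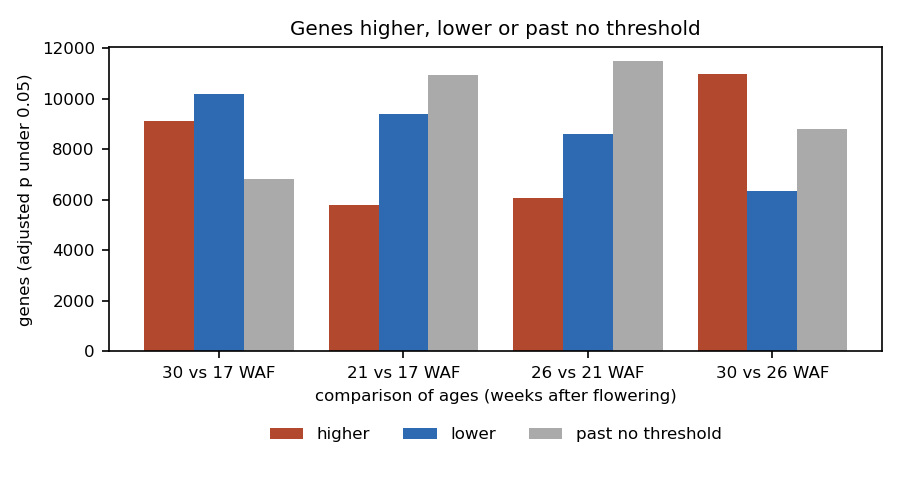
Number of tested genes (vertical axis) that were higher, lower or past no threshold at an adjusted p under 0.05, as 3 bars for each of the 4 comparisons of ages (horizontal axis). The tallest bar is that of the 11465 genes past no threshold between 21 and 26 WAF. Between 26 and 30 WAF 10984 genes were higher and 6343 lower as deposited, against 8440 and 8158 with median-of-ratios scaling.

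The comparison of 30 with 17 WAF spans the whole sampled period and asks which transcripts differ between its ends. The largest rises were in genes of anthocyanin synthesis, glutathione transfer and iridoid metabolism. A leucoanthocyanidin dioxygenase gene (LOC111368826), whose enzyme acts late in the anthocyanin pathway, rose from 0.22 ± 0.035 to 512 ± 7.46 FPKM (log2 change 8.72, SE 0.047, adjusted p = 3.4e-18). The dihydroflavonol 4-reductase gene LOC111409594, for the step before it, rose from 0.037 ± 0.035 to 111 ± 3.35 FPKM (log2 change 6.75, SE 0.057, adjusted p = 3.4e-17). The chalcone synthase J gene LOC111379443, for the entry step of flavonoid synthesis, rose from 0.63 ± 0.095 to 125 ± 4.0 FPKM (log2 change 6.27, SE 0.058, adjusted p = 6.1e-17). Glutathione S-transferase F11 (LOC111397175) rose from 8.64 ± 0.524 to 1134 ± 25.8 FPKM (log2 change 6.88, SE 0.047, adjusted p = 8.6e-18). An 8-hydroxygeraniol dehydrogenase gene (LOC111376665), for an early step of iridoid synthesis, rose from 0.35 ± 0.114 to 156 ± 2.55 FPKM (log2 change 6.87, SE 0.055, adjusted p = 2.5e-17).

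The 5 largest falls from 17 to 30 WAF included genes of regulators and of the cell wall. The transcription factor gene annotated as NAC domain-containing protein 90 (LOC111381277) went from 351 ± 5.46 to 3.55 ± 0.232 FPKM (log2 change -6.27, SE 0.040, adjusted p = 4.5e-18). TINY (LOC111366136), a member of the ethylene response factor family, went from 130.1 ± 2.95 to 1.02 ± 0.179 FPKM (log2 change -6.02, SE 0.054, adjusted p = 5.8e-17). EXORDIUM (LOC111389935) went from 113 ± 2.11 to 1.03 ± 0.442 FPKM (log2 change -5.84, SE 0.112, adjusted p = 4.7e-14). A xyloglucan endotransglucosylase/hydrolase gene (LOC111391445), for an enzyme that remodels cell wall xyloglucan, went from 117 ± 5.42 to 1.23 ± 0.294 FPKM (log2 change -5.74, SE 0.083, adjusted p = 3e-15). LOC111399221, described as keratin-associated protein 10-8 by resemblance, went from 82.7 ± 2.67 to 0.363 ± 0.085 FPKM (log2 change -5.94, SE 0.090, adjusted p = 4.8e-15).

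In the list of flavonoid and anthocyanin synthesis, 31 of 43 tested members rose, 11 fell and 1 did not pass the test (31 and 11 adjusted over the list alone). Their median was 0.95 (camera adjusted p = 3.5e-05, adjusted p = 0.036 with an estimated correlation). An abundant anthocyanidin glucosyltransferase gene (LOC111383563) went from 158 ± 2.30 to 172 ± 0.946 FPKM (log2 change 0.12, SE 0.025, adjusted p = 0.00064), and did not pass with TPM scaling (adjusted p = 0.11). ANTHOCYANINLESS 2 (LOC111391553) went from 97.9 ± 4.29 to 46.7 ± 0.491 FPKM (log2 change -1.05, SE 0.032, adjusted p = 5.9e-12). The largest fall was also in an ANTHOCYANINLESS 2 gene (LOC111387619), from 34.7 ± 1.86 to 6.33 ± 1.05 FPKM (log2 change -2.29, SE 0.090, adjusted p = 7.4e-11). ANTHOCYANINLESS 2 is a homeodomain transcription factor, not an enzyme of the pathway.

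Among the oxidative stress enzymes, 67 of 88 tested members rose, 8 fell and 13 did not pass the test (68 and 8 adjusted over the list alone). Their median was 0.45 (camera adjusted p = 3.1e-08, adjusted p = 0.036 with an estimated correlation). Catalase isozyme 3 (LOC111371766), which breaks down hydrogen peroxide, rose from 719.8 ± 10.1 to 1746 ± 12.5 FPKM (log2 change 1.28, SE 0.026, adjusted p = 1e-13). The abundant copper-zinc superoxide dismutases LOC111371474 and LOC111378800 changed, the former from 915 ± 30.9 to 784 ± 12.3 FPKM (log2 change -0.22, SE 0.040, adjusted p = 0.00024). LOC111378800 went from 525 ± 11.1 to 347 ± 7.49 FPKM (log2 change -0.60, SE 0.045, adjusted p = 5.8e-08). The largest fall was in the plastid peroxiredoxin gene LOC111412721, from 44.7 ± 1.18 to 13.8 ± 0.55 FPKM (log2 change -1.63, SE 0.040, adjusted p = 5.9e-13).

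Among genes of the light reactions of photosynthesis, 62 of 73 tested members rose, 3 fell and 8 did not pass the test (62 and 3 adjusted over the list alone). Their median was 0.97 (camera adjusted p = 8.8e-14, adjusted p = 0.19 with an estimated correlation). Chlorophyll a-b binding protein 21 (LOC111402246), a light-harvesting protein, rose from 230.5 ± 10.4 to 1074 ± 14.6 FPKM (log2 change 2.22, SE 0.051, adjusted p = 3.1e-13). The one of LHCII type 1 (LOC111407242) rose from 61.0 ± 1.82 to 480.0 ± 6.17 FPKM (log2 change 2.96, SE 0.049, adjusted p = 1.3e-14). The oxygen-evolving enhancer protein 3 gene LOC111396002 rose from 448 ± 7.0 to 918 ± 12.3 FPKM (log2 change 1.03, SE 0.038, adjusted p = 3.8e-11). A photosystem II protein D1 gene (LOC111391524) had the largest fall, from 45.9 ± 3.03 to 32.2 ± 0.771 FPKM (log2 change -0.50, SE 0.115, adjusted p = 0.0017). The 9 morning clock genes had a median log2 change of 0.25, with 5 higher and 1 lower, and the 14 evening clock genes of -0.012, with 5 higher and 5 lower.

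Of the genes of ethylene synthesis and signalling, 25 of 39 tested members rose, 9 fell and 5 did not pass the test (25 and 9 adjusted over the list alone, camera adjusted p = 0.0071, adjusted p = 0.16 with an estimated correlation). An ACC oxidase gene (LOC111370659), for the last step of ethylene synthesis, rose from 2.62 ± 0.272 to 99.7 ± 2.02 FPKM (log2 change 4.80, SE 0.084, adjusted p = 2e-14). An ACC synthase gene (LOC111380501) fell from 28.7 ± 0.674 to 0.553 ± 0.103 FPKM (log2 change -4.26, SE 0.055, adjusted p = 1.3e-15). ETHYLENE INSENSITIVE 3 genes, for regulators of ethylene responses, went from 86.4 ± 2.23 to 114 ± 1.09 FPKM in the copy LOC111401530 (log2 change 0.40, SE 0.027, adjusted p = 2.1e-08). The copy LOC111391955 was at 113 ± 5.40 to 108 ± 1.48 FPKM (adjusted p = 0.26, and 0.0061 with TPM scaling). The abundant ACC oxidase homolog 1 (LOC111387622) rose from 52.1 ± 0.291 to 98.7 ± 2.10 FPKM (log2 change 0.91, SE 0.029, adjusted p = 8.1e-12). Such homologs are related oxygenases that are not known to make ethylene. Without them, a setting chosen after the values were seen, the list was not called (adjusted p = 0.094, 0.0015 to 0.16 over all alternatives).

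The iridoid and secoiridoid list covers steps toward the bitter phenolic compounds of olive, of which oleuropein is one. In it, 19 of 31 tested members rose, 12 fell and 0 did not pass the test (19 and 12 adjusted over the list alone). Their median was 0.57 (camera adjusted p = 0.043, adjusted p = 0.31 with an estimated correlation). A 7-deoxyloganetic acid glucosyltransferase gene (LOC111376443) rose from 109 ± 3.81 to 335 ± 5.10 FPKM (log2 change 1.62, SE 0.027, adjusted p = 1.5e-14). A further 8-hydroxygeraniol dehydrogenase gene (LOC111387381) rose from 49.2 ± 0.741 to 231 ± 6.01 FPKM (log2 change 2.21, SE 0.027, adjusted p = 8.4e-16). LOC111373465 of the same description had the largest fall, from 71.8 ± 2.65 to 26.1 ± 0.465 FPKM (log2 change -1.43, SE 0.042, adjusted p = 4.1e-12). LOC111394633, described as a steroid 5-beta-reductase, a family that includes iridoid synthase, went from 102 ± 2.68 to 94.0 ± 1.77 FPKM (log2 change -0.11, SE 0.027, adjusted p = 0.0023). The call of this list ended with a pseudocount of 0.1 (adjusted p = 0.050), a stricter filter (0.21) and median-of-ratios scaling (0.060, 0.022 to 0.31 over all alternatives).

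In the jasmonate response list, 4 of 27 tested members rose, 13 fell and 10 did not pass the test (4 and 13 adjusted over the list alone). Their median was -0.32 (camera adjusted p = 0.036, adjusted p = 0.17 with an estimated correlation). Without a filter on low values it was not called (adjusted p = 0.16, 0.017 to 0.17 over all alternatives). TIFY 10A genes, for repressors induced by jasmonate, fell from 408 ± 18.0 to 56.8 ± 3.11 FPKM in the copy LOC111404294 (log2 change -2.83, SE 0.052, adjusted p = 3.2e-14). The copy LOC111366098 fell from 315 ± 19.2 to 88.4 ± 3.44 FPKM (log2 change -1.82, SE 0.059, adjusted p = 9e-12). TIFY 10B (LOC111366878) was at 151 ± 9.16 to 145 ± 7.37 FPKM (adjusted p = 0.41, and 0.030 with TPM scaling). A jasmonate O-methyltransferase gene (LOC111394434) rose from 63.5 ± 1.45 to 87.6 ± 3.23 FPKM (log2 change 0.46, SE 0.038, adjusted p = 1.5e-07).

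Marker lists of other tissues were measured beside these groups. Among cuticle and wax genes, typical of the epidermis, 23 of 44 tested members rose, 15 fell and 6 did not pass the test (24 and 16 adjusted over the list alone). Their median was 0.36 (camera adjusted p = 0.017, adjusted p = 0.20 with an estimated correlation), and the list was not called without a filter (adjusted p = 0.056, 0.0062 to 0.20 over all alternatives). Epidermal identity genes of the HD-ZIP IV class, a set chosen after the cuticle result between 26 and 30 WAF was seen, had a median of -0.52, with 5 of 17 higher and 11 lower. Among lignin and secondary wall genes, typical of endocarp and vessels, 12 of 32 tested members rose, 14 fell and 6 did not pass the test (12 and 14 adjusted over the list alone). Their median was -0.12 against an upward test (camera adjusted p = 0.93, adjusted p = 0.95 with an estimated correlation). Among seed storage protein genes, 6 of 9 tested members rose, 3 fell and 0 did not pass the test (6 and 3 adjusted over the list alone, camera adjusted p = 0.30, adjusted p = 0.39 with an estimated correlation).

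In all, 9122 genes were higher and 10178 lower at 30 than at 17 WAF, and 6831 did not pass. Higher genes made up 47.3% of those called, and 51.2% with median-of-ratios scaling, which called 9850 higher and 9398 lower. With a stricter filter, which tests fewer genes, 6786 were higher and 6568 lower. Of the 40 lists, 16 were called by camera, 14 up and 2 down, of which 2 held with an estimated correlation. With 3 libraries per age and no statement that they came from separate trees, the errors cover only the spread between these samples.

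**Figure D2:**
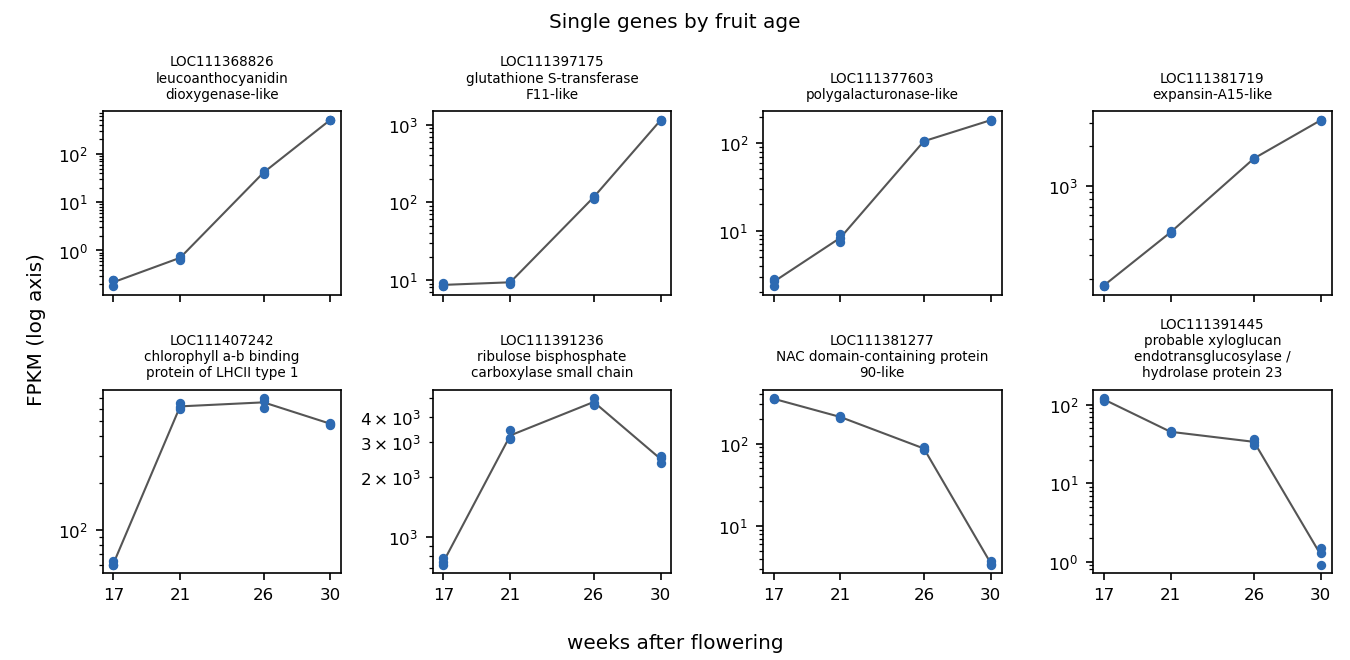
FPKM on a log axis (vertical, its range differs between panels) against weeks after flowering (horizontal) for 8 genes, 1 per panel, with a point for each of the 12 libraries and a line through the mean of each age. Leucoanthocyanidin dioxygenase (LOC111368826) goes from a mean of 0.22 ± 0.035 FPKM to 512 ± 7.46 FPKM, and the NAC gene LOC111381277 from 351 ± 5.46 to 3.55 ± 0.232 FPKM.

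Between 17 and 21 WAF most tested genes of the light reactions, the Calvin cycle and chlorophyll synthesis rose. Most genes of plastid fatty acid synthesis, the mevalonate pathway and the synthesis of squalene, sterols and triterpenes fell. In the list of the light reactions, 67 of 73 tested members rose, 0 fell and 6 did not pass the test (67 and 0 adjusted over the list alone). Their median was 1.24 (camera adjusted p = 3e-36, adjusted p = 0.063 with an estimated correlation). A photosystem I reaction center subunit VI gene (LOC111368014) rose from 2.59 ± 0.628 to 35.0 ± 2.52 FPKM (log2 change 3.34, SE 0.10, adjusted p = 2.3e-11). The gene of the LHCII type 1 chlorophyll a-b binding protein (LOC111407242) rose from 61.0 ± 1.82 to 620.3 ± 28.1 FPKM (log2 change 3.32, SE 0.049, adjusted p = 1e-13). Chlorophyll a-b binding protein 21 (LOC111402246) rose from 230.5 ± 10.4 to 1202 ± 43.0 FPKM (log2 change 2.38, SE 0.051, adjusted p = 1.9e-12). Oxygen-evolving enhancer protein 3 (LOC111396002) rose from 448 ± 7.0 to 1471 ± 43.6 FPKM (log2 change 1.71, SE 0.038, adjusted p = 2.3e-12). In the same comparison the 9 morning clock genes had a median log2 change of -0.103, with 2 higher and 5 lower, and the 14 evening clock genes of -0.013, with 4 higher and 4 lower.

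In the Calvin cycle list, for carbon fixation, 12 of 14 tested members rose, 2 fell and 0 did not pass the test (12 and 2 adjusted over the list alone). Their median was 1.18 (camera adjusted p = 1.8e-07, adjusted p = 0.036 with an estimated correlation). A small chain gene of Rubisco, the carbon-fixing enzyme (LOC111391236), rose from 751 ± 28.6 to 3232 ± 177 FPKM (log2 change 2.10, SE 0.047, adjusted p = 2.4e-12). Rubisco activase (LOC111405975) rose from 65.3 ± 0.879 to 228 ± 5.64 FPKM (log2 change 1.78, SE 0.036, adjusted p = 9.1e-13). Plastid glyceraldehyde-3-phosphate dehydrogenase B (LOC111380808) rose from 19.0 ± 0.789 to 114 ± 1.76 FPKM (log2 change 2.53, SE 0.036, adjusted p = 1e-13). Another Rubisco small chain gene (LOC111390908) fell from 339.5 ± 7.47 to 243 ± 7.67 FPKM (log2 change -0.48, SE 0.037, adjusted p = 1.7e-07). In the chlorophyll synthesis list, 19 of 28 tested members rose, 4 fell and 5 did not pass the test (19 and 4 adjusted over the list alone, camera adjusted p = 1.2e-06, adjusted p = 0.036 with an estimated correlation). The chlorophyll breakdown list rose as well, with 11 of 17 tested members higher, 2 lower and 4 that did not pass the test. Their median was 0.33 (camera adjusted p = 0.00058, adjusted p = 0.036 with an estimated correlation).

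In the list of plastid fatty acid synthesis, 5 of 49 tested members rose, 39 fell and 5 did not pass the test (5 and 39 adjusted over the list alone). Their median was -0.45 (camera adjusted p = 3.2e-07, adjusted p = 0.063 with an estimated correlation). The stearoyl-ACP desaturase gene LOC111375456, for the enzyme that makes the precursor of oleic acid, fell from 1911 ± 21.5 to 1185 ± 7.41 FPKM (log2 change -0.69, SE 0.024, adjusted p = 9.9e-11). The acyl carrier protein 1 gene LOC111375813 went from 1952 ± 76.3 to 1809 ± 26.1 FPKM (log2 change -0.11, SE 0.037, adjusted p = 0.022). It did not pass without a filter (adjusted p = 0.16) or with median-of-ratios scaling (0.60). The same held without library B (0.10) or C (0.053) of 17 WAF or C of 21 WAF (0.070). Another, LOC111382153, went from 1295 ± 62.9 to 975 ± 39.7 FPKM (log2 change -0.41, SE 0.042, adjusted p = 2.7e-06). The largest fall was in a ketoacyl-ACP synthase I gene (LOC111371731), from 5.56 ± 0.337 to 1.53 ± 0.177 FPKM (log2 change -1.38, SE 0.071, adjusted p = 3.6e-09). The largest rise was in another desaturase gene (LOC111388674), from 10.1 ± 0.633 to 19.1 ± 0.441 FPKM (log2 change 0.86, SE 0.061, adjusted p = 7.9e-08).

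Of the mevalonate pathway, which supplies isoprenoid units in the cytosol, 2 of 27 tested members rose, 19 fell and 6 did not pass the test (2 and 19 adjusted over the list alone, camera adjusted p = 0.0019, adjusted p = 0.063 with an estimated correlation). Hydroxymethylglutaryl-CoA synthase (LOC111407520) fell from 183 ± 4.73 to 78.7 ± 1.6 FPKM (log2 change -1.21, SE 0.038, adjusted p = 3.4e-11). Cytosolic acetyl-CoA acetyltransferase 1 (LOC111390947) fell from 517 ± 4.17 to 322 ± 10.1 FPKM (log2 change -0.68, SE 0.029, adjusted p = 6.5e-10). Farnesyl pyrophosphate synthase 1 (LOC111396906) fell from 242 ± 2.1 to 199 ± 1.02 FPKM (log2 change -0.29, SE 0.026, adjusted p = 9.8e-07). Isopentenyl-diphosphate isomerase I (LOC111379751) went from 246 ± 4.94 to 233 ± 5.19 FPKM (log2 change -0.08, SE 0.027, adjusted p = 0.022), but turned to 0.002 with median-of-ratios scaling (adjusted p = 0.96). It did not pass without library A (0.073) or B (0.063) of 17 WAF or B of 21 WAF (0.10). A hydroxymethylglutaryl-CoA reductase gene (LOC111410512) rose from 39.0 ± 0.576 to 49.8 ± 2.29 FPKM (log2 change 0.34, SE 0.040, adjusted p = 9.6e-06).

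Downstream, in the list of squalene, sterol and triterpene synthesis, 3 of 30 tested members rose, 21 fell and 6 did not pass the test (3 and 21 adjusted over the list alone). Their median was -0.55 (camera adjusted p = 0.00063, adjusted p = 0.036 with an estimated correlation). Beta-amyrin 28-oxidases make oleanolic acid, a triterpenoid of olive fruit. Their genes LOC111407310, LOC111374953 and LOC111365629 fell, the last-named from 130.0 ± 1.08 to 109.8 ± 4.7 FPKM (log2 change -0.24, SE 0.033, adjusted p = 4.1e-05). LOC111407310 fell from 378 ± 5.34 to 164 ± 6.10 FPKM (log2 change -1.20, SE 0.034, adjusted p = 1.7e-11). LOC111374953 fell from 235 ± 3.76 to 141 ± 4.20 FPKM (log2 change -0.73, SE 0.029, adjusted p = 3.5e-10). The largest fall was in the low-level copy LOC111374946, from 7.21 ± 0.442 to 2.08 ± 0.305 FPKM (log2 change -1.42, SE 0.085, adjusted p = 1.6e-08). A cycloartenol synthase gene (LOC111372683), of the sterol branch, rose from 18.5 ± 0.48 to 26.3 ± 0.484 FPKM (log2 change 0.48, SE 0.033, adjusted p = 6.3e-08).

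In the iridoid and secoiridoid list, from 17 to 21 WAF, 16 of 31 tested members rose, 8 fell and 7 did not pass the test (16 and 9 adjusted over the list alone). Their median was 0.17 (camera adjusted p = 0.0068, adjusted p = 0.20 with an estimated correlation). Among carotenoid synthesis genes, 10 of 20 tested members rose, 4 fell and 6 did not pass the test (11 and 4 adjusted over the list alone). Their median was 0.15 (camera adjusted p = 0.039, adjusted p = 0.13 with an estimated correlation). Of the tocopherol synthesis genes, 5 of 8 tested members rose, 0 fell and 3 did not pass the test (5 and 0 adjusted over the list alone). Their median was 0.27 (camera adjusted p = 0.039, adjusted p = 0.14 with an estimated correlation). This call ended with a stricter filter (adjusted p = 0.072) and without library A of 21 WAF (0.059, 0.017 to 0.14 over all alternatives). In the plastid isoprenoid (MEP) pathway, 11 of 23 tested members rose, 6 fell and 6 did not pass the test (11 and 6 adjusted over the list alone), and camera did not call the list (camera adjusted p = 0.074, adjusted p = 0.16 with an estimated correlation).

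In the cell cycle and replication list, 14 of 109 tested members rose, 62 fell and 33 did not pass the test (15 and 62 adjusted over the list alone). Their median was -0.21 (camera adjusted p = 0.039, adjusted p = 0.23 with an estimated correlation). The call ended with a stricter filter (adjusted p = 0.10), without library A of 17 WAF (0.051) and without library C of 21 WAF (0.075, 0.019 to 0.23 over all alternatives). The abundant histone H3.3 gene LOC111371174 fell from 358 ± 25.8 to 234 ± 14.9 FPKM (log2 change -0.61, SE 0.059, adjusted p = 1.7e-06). Its paralog LOC111397071 went from 194 ± 6.19 to 166 ± 8.33 FPKM (log2 change -0.23, SE 0.058, adjusted p = 0.0049, and 0.067 with median-of-ratios scaling). Another, LOC111401165, went from 246 ± 8.84 to 230.1 ± 4.33 FPKM (log2 change -0.10, SE 0.033, adjusted p = 0.024). The latter did not pass with median-of-ratios scaling (adjusted p = 0.76), without library A of 17 WAF (0.10) or without library C of 21 WAF (0.088). The largest rise was in cyclin-dependent kinase C-2 (LOC111391459), from 27.9 ± 0.94 to 59.0 ± 1.65 FPKM (log2 change 1.05, SE 0.038, adjusted p = 1.4e-10). Cyclin-dependent kinase inhibitor 5 (LOC111371579) had the largest fall, from 8.14 ± 0.524 to 2.76 ± 0.176 FPKM (log2 change -1.28, SE 0.084, adjusted p = 4e-08). The former belongs to kinases of transcription and the latter restrains the cycle. Only 62 of the 109 tested members fit the list's name, and camera called these downward too (adjusted p = 0.019). From 26 to 30 WAF, 62 of the 109 rose and 21 fell, and the list was not called (camera adjusted p = 0.098). The members that fit the name were called upward there (camera adjusted p = 0.0093), in a setting chosen after the values were seen.

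Among jasmonate response genes, 13 of 27 tested members rose, 7 fell and 7 did not pass the test (13 and 7 adjusted over the list alone). Their median was 0.12 (camera adjusted p = 0.036, adjusted p = 0.17 with an estimated correlation), and the list was not called with a stricter filter (adjusted p = 0.16, 0.026 to 0.17 over all alternatives).

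Of the single genes with the largest changes between 17 and 21 WAF, beta-D-xylosidase 1 (LOC111371327), a cell wall enzyme, rose from 46.9 ± 1.93 to 395 ± 10.2 FPKM (log2 change 3.05, SE 0.032, adjusted p = 7.6e-15). SULFUR DEFICIENCY-INDUCED 1 (LOC111384902) rose from 5.70 ± 0.364 to 59.1 ± 0.904 FPKM (log2 change 3.17, SE 0.056, adjusted p = 3.7e-13). The high affinity nitrate transporter 2.7 gene LOC111381300 rose from 0.863 ± 0.153 to 14.7 ± 0.195 FPKM (log2 change 3.07, SE 0.057, adjusted p = 5.2e-13). Dehydrin DHN1 (LOC111379830), of a family of proteins made under drought and cold, fell from 2324 ± 63.7 to 296 ± 11.7 FPKM (log2 change -2.97, SE 0.043, adjusted p = 1e-13). Inositol oxygenase 1 (LOC111367291) fell from 125 ± 6.92 to 11.7 ± 0.726 FPKM (log2 change -3.30, SE 0.050, adjusted p = 1e-13). An EG45-like gene (LOC111382508) fell from 53.5 ± 3.31 to 4.71 ± 0.463 FPKM (log2 change -3.26, SE 0.081, adjusted p = 5.4e-12). A proline-rich cell wall protein gene (LOC111374924) fell from 30.7 ± 4.74 to 2.66 ± 0.263 FPKM (log2 change -3.11, SE 0.096, adjusted p = 3.3e-11). Gibberellin-regulated protein 4 (LOC111376141) fell from 32.5 ± 1.01 to 2.94 ± 0.286 FPKM (log2 change -3.09, SE 0.052, adjusted p = 2.6e-13).

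Of the markers of other tissues, cuticle and wax genes came first, where 8 of 44 tested members rose, 26 fell and 10 did not pass the test (8 and 26 adjusted over the list alone). Their median was -0.36 (camera adjusted p = 0.028, adjusted p = 0.23 with an estimated correlation), and the list was not called with a stricter filter (adjusted p = 0.26, 0.014 to 0.26 over all alternatives). The 17 epidermal identity genes had a median of -0.195, with 5 higher and 11 lower. Among lignin and secondary wall genes, 11 of 32 tested members rose, 14 fell and 7 did not pass the test (12 and 14 adjusted over the list alone). Their median was -0.05, and 0.015 with median-of-ratios scaling, against an upward test (camera adjusted p = 0.82, adjusted p = 0.87 with an estimated correlation). Among seed storage protein genes, 2 of 9 tested members rose, 4 fell and 3 did not pass the test (2 and 4 adjusted over the list alone, camera adjusted p = 0.83, adjusted p = 0.86 with an estimated correlation).

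Across all genes, 5808 were higher and 9378 lower at 21 than at 17 WAF, and 10945 did not pass. By at least 2-fold, 477 of these were higher and 585 lower. The share of higher genes among those called was 38.2%, and 50.3% with median-of-ratios scaling, which called 7430 higher and 7332 lower. Camera called 15 lists, 10 up and 5 down, and 4 held with an estimated correlation.

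Between 21 and 26 WAF a gene of anthocyanin synthesis and a gene of pectin breakdown were among the 5 largest rises. The leucoanthocyanidin dioxygenase gene LOC111368826 rose from 0.707 ± 0.065 to 41.4 ± 2.32 FPKM (log2 change 4.63, SE 0.047, adjusted p = 4.6e-15). A polygalacturonase gene (LOC111377603), for an enzyme that cuts pectin, rose from 8.35 ± 0.871 to 105 ± 0.907 FPKM (log2 change 3.51, SE 0.063, adjusted p = 3.2e-13). Secoisolariciresinol dehydrogenase genes, described by an enzyme of lignan synthesis, rose from 0.84 ± 0.234 to 31.1 ± 7.16 FPKM in the copy LOC111412681 (log2 change 4.11, SE 0.192, adjusted p = 2.4e-09). The copy LOC111412273 rose from 22.1 ± 1.59 to 342 ± 15.5 FPKM (log2 change 3.89, SE 0.044, adjusted p = 1.2e-14). LOC111412272 of the same description rose from 47.0 ± 0.623 to 546 ± 17.1 FPKM (log2 change 3.51, SE 0.029, adjusted p = 5.7e-16).

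The 5 largest falls covered genes of several kinds. LOC111399221, the gene described as keratin-associated protein 10-8, went from 16.02 ± 1.65 to 1.24 ± 0.265 FPKM (log2 change -2.93, SE 0.090, adjusted p = 4.5e-11). Gibberellin 2-beta-dioxygenase 8 (LOC111368538), whose enzyme family inactivates gibberellins, went from 10.8 ± 0.937 to 1.81 ± 0.47 FPKM (log2 change -2.09, SE 0.126, adjusted p = 2.5e-08). The calcium-binding protein gene CML19 (LOC111378369) went from 60.1 ± 0.919 to 13.96 ± 0.65 FPKM (log2 change -2.03, SE 0.108, adjusted p = 7.7e-09). A glycine-rich RNA-binding protein gene (LOC111394597) went from 1144 ± 31.1 to 279.2 ± 5.48 FPKM (log2 change -2.03, SE 0.037, adjusted p = 3.2e-13). A heavy metal-associated isoprenylated protein gene (LOC111370985) went from 144 ± 7.57 to 37.1 ± 2.73 FPKM (log2 change -1.93, SE 0.067, adjusted p = 1.5e-10).

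In the list of pectin and wall loosening enzymes, 57 of 120 tested members rose, 29 fell and 34 did not pass the test (59 and 30 adjusted over the list alone). Their median was 0.16 (camera adjusted p = 1.0e-04, adjusted p = 0.036 with an estimated correlation). Expansin-A15 (LOC111381719), of a family that loosens cell walls, rose from 448 ± 11.7 to 1617 ± 18.7 FPKM (log2 change 1.85, SE 0.026, adjusted p = 3.7e-14). Expansin-A8 (LOC111384671) rose from 76.2 ± 0.691 to 267 ± 3.57 FPKM (log2 change 1.80, SE 0.035, adjusted p = 6.3e-13). A beta-galactosidase gene (LOC111387481) rose from 321 ± 5.37 to 496 ± 2.41 FPKM (log2 change 0.62, SE 0.027, adjusted p = 1e-09). A xyloglucan endotransglucosylase/hydrolase gene (LOC111387295) fell from 10.2 ± 0.737 to 2.24 ± 0.15 FPKM (log2 change -1.79, SE 0.064, adjusted p = 1.9e-10). From the start to the end of the series expansin-A15 rose, with 177 ± 2.62 FPKM at 17 WAF and 3142 ± 33.8 FPKM at 30 WAF (log2 change 4.14, SE 0.026, adjusted p = 4.5e-18).

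In the flavonoid and anthocyanin list, 28 of 43 tested members rose, 11 fell and 4 did not pass the test (28 and 12 adjusted over the list alone). Their median was 0.50 (camera adjusted p = 0.00012, adjusted p = 0.036 with an estimated correlation). The anthocyanidin glucosyltransferase gene LOC111383563 fell from 198 ± 3.98 to 175 ± 3.12 FPKM (log2 change -0.18, SE 0.025, adjusted p = 6.5e-05). The transcription factor gene ANTHOCYANINLESS 2 fell in the copy LOC111391553, from 56.6 ± 0.674 to 41.8 ± 0.634 FPKM (log2 change -0.43, SE 0.032, adjusted p = 2.1e-07). The copy LOC111410766 had the largest fall, from 23.4 ± 1.66 to 8.07 ± 0.207 FPKM (log2 change -1.42, SE 0.051, adjusted p = 1.9e-10). Among oxidative stress enzymes, 50 of 88 tested members rose, 12 fell and 26 did not pass the test (51 and 12 adjusted over the list alone, camera adjusted p = 4.3e-08, adjusted p = 0.036 with an estimated correlation). Glutathione S-transferase F11 (LOC111397175) rose from 9.34 ± 0.48 to 116 ± 5.13 FPKM (log2 change 3.505, SE 0.047, adjusted p = 2.7e-14). Catalase isozyme 3 (LOC111371766) rose from 1515 ± 26.9 to 1926 ± 48.3 FPKM (log2 change 0.34, SE 0.026, adjusted p = 2.4e-07). The superoxide dismutase gene LOC111371474 fell from 1086 ± 33.6 to 919 ± 48.6 FPKM (log2 change -0.24, SE 0.040, adjusted p = 0.00021). LOC111403922, of a plastid superoxide dismutase, had the largest fall, from 5.87 ± 0.286 to 3.93 ± 0.389 FPKM (log2 change -0.48, SE 0.083, adjusted p = 0.00030). The copper-zinc gene LOC111378800 went from 353 ± 16.5 to 313 ± 19.8 FPKM (log2 change -0.17, SE 0.045, adjusted p = 0.0058, and 0.12 with median-of-ratios scaling).

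In the list of plastid fatty acid synthesis, 35 of 49 tested members rose, 7 fell and 7 did not pass the test (36 and 7 adjusted over the list alone). Their median was 0.23 (camera adjusted p = 1.1e-08, adjusted p = 0.048 with an estimated correlation). The stearoyl-ACP desaturase gene LOC111375456 rose from 1185 ± 7.41 to 1748 ± 14.6 FPKM (log2 change 0.56, SE 0.024, adjusted p = 1.1e-09). The acyl carrier protein 1 gene LOC111375813 rose from 1809 ± 26.1 to 2508 ± 82.6 FPKM (log2 change 0.47, SE 0.037, adjusted p = 2.9e-07). Its paralog LOC111382153 rose from 975 ± 39.7 to 1188 ± 47.0 FPKM (log2 change 0.28, SE 0.042, adjusted p = 8.5e-05). A ketoacyl-ACP synthase II gene (LOC111411906) rose from 43.1 ± 0.835 to 75.1 ± 1.17 FPKM (log2 change 0.79, SE 0.028, adjusted p = 2.1e-10). A FabG-like ketoacyl-ACP reductase gene (LOC111397481) fell from 7.18 ± 0.279 to 4.85 ± 0.397 FPKM (log2 change -0.48, SE 0.082, adjusted p = 0.00027).

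Among cytosolic ribosomal protein genes, 15 of 350 tested members rose, 242 fell and 93 did not pass the test (15 and 249 adjusted over the list alone). Their median was -0.23 (camera adjusted p = 4.4e-10, adjusted p = 0.23 with an estimated correlation). The 60S protein gene L19-3 (LOC111403559) fell from 613 ± 5.25 to 462 ± 22.9 FPKM (log2 change -0.41, SE 0.041, adjusted p = 3.3e-06). L35 (LOC111399732) fell from 369.5 ± 19.0 to 306 ± 23.3 FPKM (log2 change -0.27, SE 0.053, adjusted p = 0.00076). L27a-3 (LOC111398827) was at 278.97 ± 16.8 to 299.8 ± 26.5 FPKM (adjusted p = 0.14). It passed upward with TPM scaling (0.042), median-of-ratios scaling (0.027) and library weights (0.028). The same held without library A of 21 WAF (0.044) or B of 26 WAF (0.0098). L10 (LOC111405928) had the largest rise, from 22.5 ± 0.861 to 44.7 ± 4.75 FPKM (log2 change 0.96, SE 0.065, adjusted p = 7.4e-08). L5 (LOC111393728) had the largest fall, from 32.9 ± 14.5 to 13.3 ± 4.15 FPKM (log2 change -1.17, SE 0.337, adjusted p = 0.010). Many of these genes have near-identical copies, so the split of reads between copies is uncertain. The 136 genes of other small proteins had a median log2 change of -0.024 in the same comparison.

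Among jasmonate response genes, 5 of 27 tested members rose, 17 fell and 5 did not pass the test (5 and 18 adjusted over the list alone). Their median was -0.25 (camera adjusted p = 0.028, adjusted p = 0.16 with an estimated correlation).

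Of the markers of other tissues, cuticle and wax genes came first, where 9 of 44 tested members rose, 23 fell and 12 did not pass the test (9 and 24 adjusted over the list alone). Their median was -0.16, and camera did not call the list (camera adjusted p = 0.19, adjusted p = 0.41 with an estimated correlation). With a stricter filter it was called (adjusted p = 0.039, 0.039 to 0.41 over all alternatives). The 17 epidermal identity genes had a median of -0.491 and quartiles of -0.58 and -0.195, with 1 higher and 13 lower. Among lignin and secondary wall genes, 13 of 32 tested members rose, 15 fell and 4 did not pass the test (13 and 15 adjusted over the list alone). Their median was -0.17 against an upward test (camera adjusted p = 0.76, adjusted p = 0.84 with an estimated correlation). Among seed storage protein genes, 5 of 9 tested members rose, 3 fell and 1 did not pass the test (6 and 3 adjusted over the list alone, camera adjusted p = 0.33, adjusted p = 0.40 with an estimated correlation).

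Across all genes, 6064 were higher and 8602 lower at 26 than at 21 WAF, and 11465 did not pass. By at least 2-fold, 493 of these were higher and 333 lower. Higher genes made up 41.3% of those called, and 53.4% with median-of-ratios scaling, which called 7643 higher and 6673 lower. Camera called 13 lists, 11 up and 2 down, and 4 held with an estimated correlation.

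**Figure D3:**
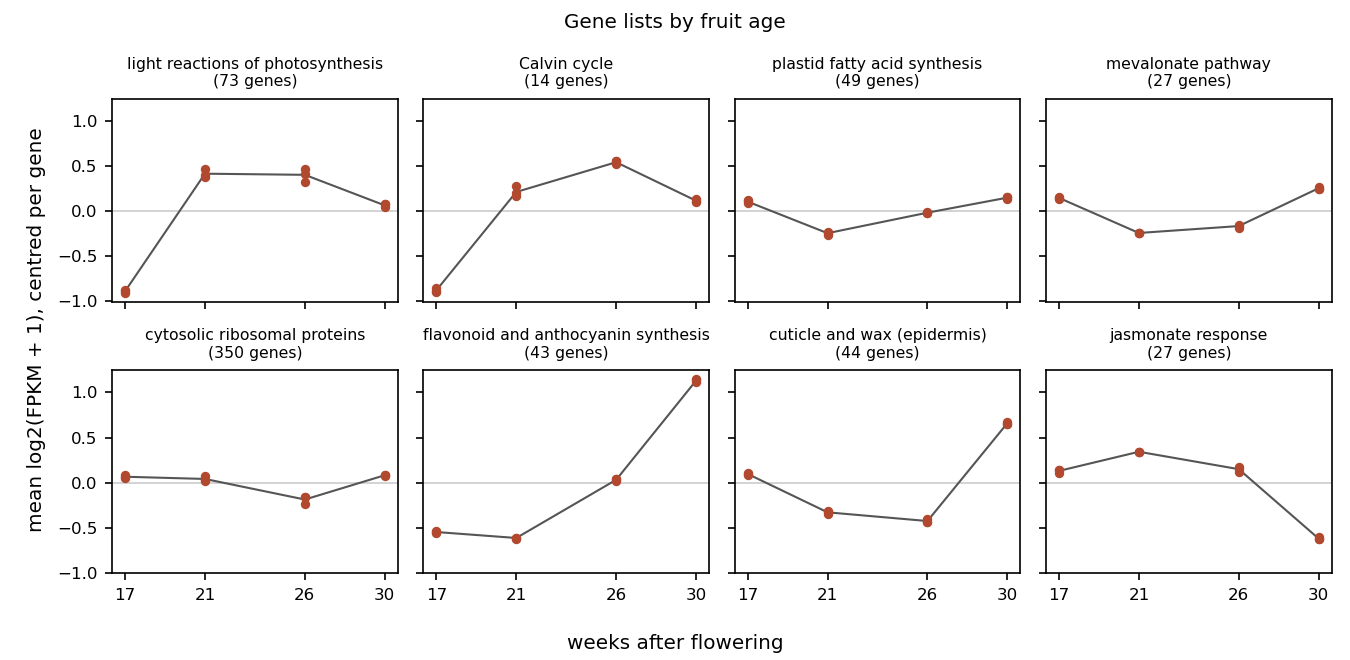
Mean log2(FPKM + 1) of 8 gene lists (vertical axis), centred on each gene's mean over the 12 libraries, against weeks after flowering (horizontal axis), with a point per library and a line through the mean of each age. The light reactions rise between 17 and 21 WAF, where 67 of 73 genes rose, and the cuticle and wax list rises between 26 and 30 WAF, where 35 of 44 genes rose.

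Between 26 and 30 WAF most tested genes of the cuticle, phenylpropanoid and anthocyanin lists rose. Most genes of the lists of photosynthesis, the lipoxygenase pathway and the jasmonate response fell. In the cuticle and wax list, whose genes are typical of the epidermis, 35 of 44 tested members rose, 4 fell and 5 did not pass the test (36 and 4 adjusted over the list alone). Their median was 0.99 (camera adjusted p = 7.1e-08, adjusted p = 0.036 with an estimated correlation). ECERIFERUM 3 (LOC111385303), for a wax alkane enzyme, rose from 264 ± 10.9 to 567 ± 1.36 FPKM (log2 change 1.10, SE 0.030, adjusted p = 3.6e-12). The elongase gene 3-ketoacyl-CoA synthase 10 (LOC111388105) rose from 197 ± 5.74 to 415 ± 14.8 FPKM (log2 change 1.07, SE 0.036, adjusted p = 3e-11). The elongase gene 3-ketoacyl-CoA synthase 11 (LOC111383577) rose from 113 ± 4.38 to 212 ± 3.54 FPKM (log2 change 0.90, SE 0.029, adjusted p = 2.4e-11). Fatty acyl-CoA reductase 3 (LOC111391318) had the largest rise, from 18.1 ± 0.611 to 169.8 ± 5.13 FPKM (log2 change 3.16, SE 0.070, adjusted p = 5e-13). Another 3-ketoacyl-CoA synthase 11 gene (LOC111398707) had the largest fall, from 37.9 ± 0.63 to 7.95 ± 0.365 FPKM (log2 change -2.12, SE 0.034, adjusted p = 2.4e-14).

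In the phenylpropanoid list, 20 of 25 tested members rose, 0 fell and 5 did not pass the test (20 and 0 adjusted over the list alone). Their median was 0.76 (camera adjusted p = 1.6e-05, adjusted p = 0.036 with an estimated correlation). A phenylalanine ammonia-lyase gene (LOC111399604), for the entry step of the pathway, rose from 3.21 ± 0.101 to 37.3 ± 0.848 FPKM (log2 change 3.19, SE 0.045, adjusted p = 8.6e-15). Cinnamate 4-monooxygenase (LOC111393218) rose from 243 ± 2.16 to 316 ± 8.37 FPKM (log2 change 0.38, SE 0.028, adjusted p = 1.1e-07). The caffeoylshikimate esterase genes LOC111370048 and LOC111394265 rose, the former from 41.3 ± 2.63 to 188 ± 5.56 FPKM (log2 change 2.16, SE 0.043, adjusted p = 1.7e-13). LOC111394265 rose from 98.8 ± 2.01 to 111 ± 1.61 FPKM (log2 change 0.17, SE 0.034, adjusted p = 0.00073), but did not pass with median-of-ratios scaling (adjusted p = 0.15).

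In the flavonoid and anthocyanin list, 27 of 43 tested members rose, 5 fell and 11 did not pass the test (27 and 5 adjusted over the list alone). Their median was 0.41 (camera adjusted p = 0.00058, adjusted p = 0.036 with an estimated correlation). Dihydroflavonol 4-reductase (LOC111409594) rose from 8.08 ± 0.365 to 111 ± 3.35 FPKM (log2 change 3.62, SE 0.057, adjusted p = 2e-14). Leucoanthocyanidin dioxygenase (LOC111368826) rose from 41.4 ± 2.32 to 512 ± 7.46 FPKM (log2 change 3.60, SE 0.047, adjusted p = 4.5e-15). ANTHOCYANINLESS 2 (LOC111391553) rose from 41.8 ± 0.634 to 46.7 ± 0.491 FPKM (log2 change 0.16, SE 0.032, adjusted p = 0.00096), but did not pass with median-of-ratios scaling (adjusted p = 0.22). The glucosyltransferase gene LOC111383563 was at 175 ± 3.12 to 172 ± 0.946 FPKM (adjusted p = 0.36). It passed downward with TPM (0.023) and median-of-ratios scaling (0.00061). An anthocyanidin glucoside glucosyltransferase gene (LOC111386713) had the largest fall, from 88.1 ± 3.57 to 58.7 ± 0.137 FPKM (log2 change -0.58, SE 0.036, adjusted p = 1.8e-08).

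Among genes of the light reactions, 5 of 73 tested members rose, 52 fell and 16 did not pass the test (5 and 52 adjusted over the list alone). Their median was -0.30 (camera adjusted p = 7.6e-10, adjusted p = 0.26 with an estimated correlation). Oxygen-evolving enhancer protein 3 (LOC111396002) fell from 1432 ± 82.3 to 918 ± 12.3 FPKM (log2 change -0.64, SE 0.038, adjusted p = 1.1e-08). The light-harvesting genes LOC111402246 and LOC111407242 fell, the former from 1497 ± 118 to 1074 ± 14.6 FPKM (log2 change -0.48, SE 0.051, adjusted p = 3.5e-06). LOC111407242 fell from 658 ± 50.3 to 480.0 ± 6.17 FPKM (log2 change -0.45, SE 0.049, adjusted p = 4e-06). The largest fall was in the CP24 10A gene LOC111385978, from 9.20 ± 0.935 to 3.55 ± 0.296 FPKM (log2 change -1.16, SE 0.074, adjusted p = 1.9e-08). The largest rise was in the photosystem II W protein gene LOC111375547, from 4.37 ± 0.146 to 5.59 ± 0.171 FPKM (log2 change 0.30, SE 0.081, adjusted p = 0.0061). In the Calvin cycle list, 0 of 14 tested members rose, 11 fell and 3 did not pass the test (0 and 11 adjusted over the list alone, camera adjusted p = 3.5e-05, adjusted p = 0.048 with an estimated correlation). Morning clock genes rose in this step, with 7 of 9 higher and 1 lower, a median of 0.42 and quartiles of 0.27 and 0.54. The 14 evening clock genes had a median of -0.084, with 4 higher and 4 lower. The labels used here give no hour of collection, so hour and age cannot be told apart in this step.

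The lipoxygenase pathway forms oil aroma volatiles and jasmonates from fatty acids. In its list, 7 of 23 tested members rose, 15 fell and 1 did not pass the test (7 and 15 adjusted over the list alone). Their median was -0.34 (camera adjusted p = 0.0058, adjusted p = 0.063 with an estimated correlation). The 13-lipoxygenase genes LOC111392344 and LOC111393284 fell, the former from 1448 ± 22.6 to 740.1 ± 14.4 FPKM (log2 change -0.97, SE 0.027, adjusted p = 4.3e-12). LOC111393284 fell from 251 ± 21.6 to 84.5 ± 1.18 FPKM (log2 change -1.56, SE 0.060, adjusted p = 1.2e-10). Hydroperoxide lyase (LOC111368519) fell from 429.8 ± 15.4 to 187 ± 5.97 FPKM (log2 change -1.20, SE 0.034, adjusted p = 6.3e-12). The largest fall was in a further 13-lipoxygenase gene (LOC111366164), from 69.3 ± 0.839 to 12.6 ± 0.251 FPKM (log2 change -2.38, SE 0.032, adjusted p = 5.7e-15). The largest rise was in allene oxide synthase 1 (LOC111408828), from 3.25 ± 0.346 to 6.84 ± 0.354 FPKM (log2 change 0.89, SE 0.067, adjusted p = 1.2e-07).

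In the jasmonate response list, 7 of 27 tested members rose, 16 fell and 4 did not pass the test (7 and 16 adjusted over the list alone, camera adjusted p = 0.0016, adjusted p = 0.073 with an estimated correlation). TIFY 5A (LOC111402233) fell from 59.8 ± 2.81 to 3.197 ± 0.678 FPKM (log2 change -3.87, SE 0.093, adjusted p = 1.1e-12). The TIFY 10A gene LOC111404294 fell from 192 ± 12.8 to 56.8 ± 3.11 FPKM (log2 change -1.74, SE 0.052, adjusted p = 9.7e-12). Its paralog LOC111366098 fell from 145 ± 12.6 to 88.4 ± 3.44 FPKM (log2 change -0.70, SE 0.059, adjusted p = 3.1e-07). TIFY 10B (LOC111366878) rose from 99.0 ± 7.49 to 145 ± 7.37 FPKM (log2 change 0.55, SE 0.056, adjusted p = 2.2e-06). JAR1 (LOC111377782), for the enzyme that conjugates jasmonic acid to isoleucine, rose from 21.3 ± 1.05 to 37.6 ± 0.498 FPKM (log2 change 0.79, SE 0.035, adjusted p = 6.1e-10).

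In the mevalonate pathway, 20 of 27 tested members rose, 4 fell and 3 did not pass the test (21 and 4 adjusted over the list alone). Their median was 0.47 (camera adjusted p = 0.0033, adjusted p = 0.063 with an estimated correlation). Cytosolic acetyl-CoA acetyltransferase 1 (LOC111390947) rose from 422 ± 5.54 to 654 ± 18.7 FPKM (log2 change 0.63, SE 0.029, adjusted p = 8.7e-10). Isopentenyl-diphosphate isomerase I (LOC111379751) rose from 256 ± 2.21 to 299.9 ± 6.73 FPKM (log2 change 0.23, SE 0.027, adjusted p = 1e-05). Farnesyl pyrophosphate synthase 1 (LOC111396906) rose from 271 ± 9.09 to 298 ± 2.31 FPKM (log2 change 0.14, SE 0.026, adjusted p = 0.00059), but did not pass with median-of-ratios scaling (adjusted p = 0.35). Genes of hydroxymethylglutaryl-CoA reductase, the rate-limiting enzyme, took both extremes. LOC111401248 rose from 15.0 ± 0.878 to 73.5 ± 2.81 FPKM (log2 change 2.22, SE 0.051, adjusted p = 6.7e-13). LOC111409359 fell from 18.3 ± 0.73 to 5.51 ± 0.101 FPKM (log2 change -1.57, SE 0.037, adjusted p = 1e-12). In the list of squalene, sterol and triterpene synthesis, 18 of 30 tested members rose, 6 fell and 6 did not pass the test (18 and 6 adjusted over the list alone). Their median was 0.44 (camera adjusted p = 0.032, adjusted p = 0.10 with an estimated correlation), and the list was not called with a stricter filter (adjusted p = 0.092, 0.0054 to 0.10 over all alternatives). Among cytosolic ribosomal protein genes, 256 of 350 tested members rose, 9 fell and 85 did not pass the test (260 and 10 adjusted over the list alone). Their median was 0.27 (camera adjusted p = 7.7e-08, adjusted p = 0.30 with an estimated correlation). Of the 136 genes of other small proteins, 84 were higher and 9 lower, with a median of 0.25.

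Of the single genes with the largest changes, ZINC INDUCED FACILITATOR 1 (LOC111411275), for a membrane transporter, was listed at 0 in the 3 libraries of 26 WAF. Libraries A, B and C of 30 WAF had 34.79, 25.01 and 27.50 FPKM (adjusted p = 1.5e-12). Serine carboxypeptidase-like 52 (LOC111372423) was also listed at 0 in the 3 libraries of 26 WAF, and had 22.9, 18.98 and 29.86 FPKM at 30 WAF (adjusted p = 5.7e-08). GAST1 (LOC111382674) rose from 2.81 ± 0.267 to 51.8 ± 1.66 FPKM (log2 change 3.79, SE 0.084, adjusted p = 4.8e-13). Glycine-rich protein 5 (LOC111377308) rose from 1.70 ± 0.26 to 33.8 ± 1.99 FPKM (log2 change 3.69, SE 0.096, adjusted p = 2.3e-12). The transporter gene NRT1/PTR FAMILY 5.1 (LOC111403048) rose from 2.94 ± 0.283 to 47.8 ± 0.812 FPKM (log2 change 3.63, SE 0.066, adjusted p = 7.7e-14). EXORDIUM (LOC111389935) fell from 54.1 ± 3.03 to 1.03 ± 0.442 FPKM (log2 change -4.79, SE 0.112, adjusted p = 8.7e-13). LOB domain-containing protein 41 (LOC111386368) fell from 129.9 ± 3.01 to 5.19 ± 0.248 FPKM (log2 change -4.40, SE 0.039, adjusted p = 2.6e-16). The NAC gene LOC111381277 fell from 87.3 ± 2.60 to 3.55 ± 0.232 FPKM (log2 change -4.28, SE 0.040, adjusted p = 3.1e-16). The receptor kinase gene FERONIA (LOC111385922) fell from 27.6 ± 3.65 to 0.623 ± 0.27 FPKM (log2 change -4.14, SE 0.111, adjusted p = 3.1e-12). TINY (LOC111366136) fell from 33.9 ± 0.925 to 1.02 ± 0.179 FPKM (log2 change -4.11, SE 0.054, adjusted p = 4.5e-15).

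Beside the rise of cuticle genes, typical of the epidermis, the 17 epidermal identity genes of the HD-ZIP IV class had a median of 0.156, with 9 higher and 2 lower. The lists of other tissues were not called. Among lignin and secondary wall genes, 14 of 32 tested members rose, 7 fell and 11 did not pass the test (14 and 7 adjusted over the list alone). Their median was 0.06, and -0.04 with median-of-ratios scaling (camera adjusted p = 0.77, adjusted p = 0.85 with an estimated correlation). Among seed storage protein genes, 4 of 9 tested members rose, 2 fell and 3 did not pass the test (4 and 2 adjusted over the list alone, camera adjusted p = 0.76, adjusted p = 0.81 with an estimated correlation).

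Across all genes, 10984 were higher and 6343 lower at 30 than at 26 WAF, and 8804 did not pass. By at least 2-fold, 964 of these were higher and 1042 lower. Higher genes made up 63.4% of those called, and 50.8% with median-of-ratios scaling, which called 8440 higher and 8158 lower. The median log2 change of all genes was 0.10 as deposited and 0.011 with that scaling. Camera called 16 lists, 10 up and 6 down, and 5 held with an estimated correlation.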

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

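The lists without members that do not do what the list's name says were chosen after the data were seen, and the other alternatives before. Counts of all genes called higher or lower kept within 1.5 times of the values given, except that 6568 genes were lower at 30 than at 17 WAF with a stricter filter, where fewer genes were tested. Counts of changes of at least 2-fold moved more. With a pseudocount of 0.1, for example, 842 genes were higher by that size at 21 than at 17 WAF, against 477. With an estimated inter-gene correlation, 2, 4, 4 and 5 lists were called for 30 vs 17, 21 vs 17, 26 vs 21 and 30 vs 26 WAF, and the cause was not tested. Of the 153 values of named genes in single comparisons, 140 kept their call and direction under all alternatives and 13 did not. Many of these genes were picked for large changes in the same data, so this share does not carry over to other genes. The change of LOC111379751 from 17 to 21 WAF turned to 0.002 with median-of-ratios scaling, and the cause was not tested. Of the 160 results of lists, called or not, 104 kept their status in all settings and 56 changed it in some setting. With the estimated correlation alone, 45 results lost their call. Most of the 104 were thus not called to begin with, so they do not measure how stable the calls are. No list that was called, as given or in the alternative, turned the direction of its camera test there. Some lists that were not called did turn, among them heat shock proteins from 17 to 21 WAF without members that do another thing than the list's name says. Leaving out each library in turn gave 8730 to 9164 higher and 9667 to 10188 lower genes for 30 vs 17 WAF, 5231 to 5917 and 8553 to 9549 for 21 vs 17 WAF, 5565 to 6176 and 7595 to 8837 for 26 vs 21 WAF, and 10271 to 10978 and 5791 to 6304 for 30 vs 26 WAF. Lists called ranged from 14 to 16, 14 to 15, 13 to 13 and 15 to 16, and genes changed over the 4 ages from 23088 to 23336. Genes with their highest mean at 17 or 21 WAF numbered 5344 and 2831 with a stricter filter, again with fewer genes tested. Deviations from the age means correlated at -0.086 to 0.074 over the 18 pairs with the same replicate letter. Over the 36 others they correlated at -0.148 to 0.150. These values show no pairing by letter, but the labels do not say what the letters stand for, so pairing is not excluded. With the letter as a block, 9081 genes were higher and 10134 lower at 30 than at 17 WAF. The unknown depth leaves open how much of the spread is counting error.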

Other observations

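The abundant genes and the GO terms below and the test of fruit skin were chosen after the result was seen.

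A few genes of very high abundance changed between the ages. A bark storage protein A gene (LOC111384066), of a family of vegetative storage proteins, was at 5417 ± 109 FPKM at 17 WAF, 41802 ± 765 at 21 WAF, 17715 ± 67.1 at 26 WAF and 4539.7 ± 31.2 at 30 WAF (21 vs 17 WAF: log2 change 2.95, SE 0.029, adjusted p = 4.9e-15). A further gene of that description (LOC111399394) was at 2269 ± 61.2, 17537 ± 351, 7392 ± 247 and 1724 ± 26.6 FPKM at these ages (21 vs 17 WAF: log2 change 2.95, SE 0.033, adjusted p = 9.5e-15). A beta-glucosidase gene (LOC111404214) rose from 3728 ± 77.03 FPKM at 17 WAF to 10009 ± 291 FPKM at 21 WAF (log2 change 1.42, SE 0.037, adjusted p = 7.3e-12) and was at 5344 ± 109 FPKM at 30 WAF. A non-specific lipid-transfer protein 1 gene (LOC111408002) rose from 2499 ± 186 FPKM at 26 WAF to 9430.4 ± 263 FPKM at 30 WAF (log2 change 1.92, SE 0.063, adjusted p = 2.7e-11). SRC1 (LOC111387830), the most abundant gene at 17 WAF, was at 12814 ± 726, 5498 ± 392, 4428 ± 365 and 10924 ± 404 FPKM at the 4 ages.

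Of the 569 GO terms, the proteasome core complex had 14 tested genes. All 14 rose between 21 and 26 WAF (median log2 change 0.46, camera adjusted p = 6.8e-08, adjusted p = 0.21 with an estimated correlation), and all 14 rose between 26 and 30 WAF (median 0.46, adjusted p = 0.00055, 0.24 with an estimated correlation). Between 17 and 21 WAF, 1 rose and 10 fell. Proteasome subunit beta type-4 (LOC111369923) rose from 59.8 to 97.4 FPKM between 21 and 26 WAF (log2 change 0.69, SE 0.049, adjusted p = 1.2e-07). Of the 123 genes with the term ADP binding, most of them described as disease resistance proteins, 93 fell and 16 rose between 17 and 30 WAF (median -0.50, adjusted p = 2.1e-06, 0.40 with an estimated correlation). LOC111373845, described as a late blight resistance protein homolog, went from 53.3 to 8.37 FPKM (log2 change -2.54, SE 0.054, adjusted p = 1.4e-13). In the first interval, from 17 to 21 WAF, 37 of the 123 genes rose and 20 fell (median 0.057, camera adjusted p = 0.071, 0.70 with an estimated correlation). Camera called 162 terms in at least 1 comparison with its preset correlation and 0 with an estimated one, where 199 had an unadjusted p under 0.05 in at least 1 comparison.

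Cuticle and wax genes were higher at 30 than at 26 WAF, with a list median of 0.99 and quartiles of 0.18 and 1.80. Median-of-ratios scaling took the median of all tested genes to 0.011 and left 0.91 for the list, which argues against scaling as the cause. A larger share of fruit skin in the 30 WAF samples may account for part of the rise. The 17 epidermal identity genes of the HD-ZIP IV class had a median of 0.156 and quartiles of 0.05 and 0.55, with 9 higher and 2 lower. The upper of these quartiles overlaps the range of the cuticle list, so skin share and age cannot be told apart. All tested genes had a median of 0.10 in this step, with 42.0% higher and 24.3% lower. The median of the epidermal identity genes thus lay near the general shift. The 17 genes are those that passed the filter on low values in these samples, and 6 of them are in the flavonoid list. The most abundant were ANTHOCYANINLESS 2 (LOC111391553), at means of 41.8 and 46.7 FPKM, and GLABRA 2 (LOC111406410), at 23.3 and 43.0 FPKM at 26 and 30 WAF.

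Cytosolic ribosomal protein genes were lower at 26 than at 21 WAF and higher again at 30 WAF, with medians of -0.23 and 0.27. Scaling between libraries is argued against as the whole cause, since the step that kept the smallest share of its size still had a median of 0.17 with median-of-ratios scaling. A loss of short transcripts in the 26 WAF libraries could also lower these genes. The 136 genes of other small proteins had a median of -0.024 with quartiles of -0.22 and 0.21 from 21 to 26 WAF, where 42 rose and 38 fell, and of 0.25 from 26 to 30 WAF. As they went both ways in the first step, length and age cannot be told apart.

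Light reaction genes were higher at 21 than at 17 WAF, with a median of 1.24. TPM scaling left 1.18, but the summed FPKM of the libraries were close, so TPM scaling could change little. Median-of-ratios scaling took the median of all tested genes from -0.069 to 0 and gave the list a median of 1.315. The latter values argue against scaling as the cause. The labels used here give no hour of collection, and another hour at 21 WAF could shift genes that follow the day. The 9 morning clock genes had a median of -0.103 and the 14 evening genes of -0.013, while single genes moved by -0.66 to 0.73. These both-way moves decide nothing, so hour and age cannot be told apart. A change with fruit age remains open in all 3 patterns, and age goes together with the date of collection, so season and weather cannot be separated from it.

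Other splits of the libraries were counted for each result. For each pair of ages, 1 of the 10 splits of 6 libraries into 3 and 3, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real and highest other counts were 19300 and 0 genes for 30 vs 17 WAF, 15186 and 2 for 21 vs 17 WAF, 14666 and 1 for 26 vs 21 WAF, and 17327 and 1 for 30 vs 26 WAF. The lists called numbered 16 against at most 9, 15 against 10, 13 against 11 and 16 against 9, and 1 of 10 splits gave as many lists in each case. Camera with its preset correlation thus called up to 11 lists in splits in which at most 2 genes passed. These splits mix the 2 ages unequally, so part of the age difference remains while the spread within groups grows. They therefore measure neither chance nor the false calls of camera. Over the 4 ages, 1 of 100 splits of the 12 libraries into 4 groups of 3, the real one, gave 23483 genes. The highest other gave 18325. The labels do not say that the samples of an age came from separate trees, so this shows only that libraries group by age. Chance differences between the samples are not excluded by it.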
